A study of Mus musculus with 16 samples.

How the data were processed

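The series measured gene expression in cultured cortical neurons from embryonic day 16.5 C57BL/6 mice on 16 single-colour Affymetrix mouse genome 430 2.0 arrays. Per the labels' protocols, lentivirus carrying either an shRNA against c-Fos or a control shRNA against firefly luciferase was put on the cultures for 6 h on day 5 in vitro with polybrene at 6 µg per ml. On day 7 the neurons were silenced and then given KCl for 0, 1, 3 or 6 h, and 10 µg of labelled cDNA was hybridised to each array. The 8 groups, 2 shRNAs at 4 times, held 2 arrays each. The labels call the arrays of a group biological replicates but do not say whether they came from separate dissections, so p-values measure the spread between these arrays.

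The deposited table held 1 linear intensity per probe set and array, between 0.51 and 23935.63. Per the labels, the arrays went through Affymetrix processing. The summarization software, its version and its scaling target are not given in the sources used here. Array medians of the deposited intensity ran from 104.75 to 118.56, a difference of 13.2%. The rules, contrasts, gene lists and alternatives were fixed before the data were examined, except where stated. The normalization rule called for quantile normalization where medians differed by more than 10%, so log2(intensity + 16) was quantile normalized. Changes are on that scale, which understates the change of dim genes. No detection calls were analysed here, so a dim probe set has no tested floor, and the number of arrays limits the precision.

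Of 45101 probe sets, 64 were array controls and stayed out of the tests. Of the other 45037, the platform annotation gave 1 gene for 34945, several for 932 and none for 9160. Symbols were set against a RefSeq gene table through the Entrez number, and 34741 of the probe sets with 1 gene matched. A gene was represented by its probe set with the highest mean over all arrays, and 9009 of 18194 genes had more than 1 probe set. Genes above the 30th percentile of the mean of all non-control probe sets were tested, which left 13916 genes. In 400 genes, probe sets of one gene were called in opposite directions for KCl at 6 h with control shRNA, and in 40 genes for c-Fos shRNA at 0 h.

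limma 3.58.1 in R 4.3.3 fitted the mean of each of the 8 groups over all 16 arrays, with 8 residual degrees of freedom, using lmFit and eBayes with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. All adjusted p-values of single genes come from this fit unless another is named. The contrasts were KCl at 1, 3 and 6 h against 0 h for each shRNA, c-Fos shRNA against control shRNA at each of the 4 times and on their average, and the shRNA by KCl interaction at 1, 3 and 6 h with an F test over the 3. An interaction is the KCl change with c-Fos shRNA minus that with control shRNA. KCl-induced genes were those called in the KCl response averaged over both shRNAs with a log2 change of at least 1, leaving out Fos.

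Gene groups were 22 fixed lists with 292 symbols, of which 269 were named on the array and 239 were tested. The lists covered early-response transcription factors, early-response signalling and effector genes, late activity-induced neuronal effectors, AP-1 subunits, genes described as AP-1 targets, neuropeptides, voltage-gated potassium channels, ionotropic transmitter receptors, postsynaptic scaffold, the unfolded protein response, cholesterol synthesis, glycolysis, interferon response, p53 targets and apoptosis, and markers of astrocytes, microglia, the oligodendrocyte lineage, vascular cells and fibroblasts, progenitors and dividing cells, excitatory neurons, inhibitory neurons and all neurons. Lists were tested against the other genes with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry beside it. Fos was left out of the lists wherever the c-Fos shRNA entered the contrast.

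The genes named by rule were Fos first, then for each KCl contrast the 15 largest rises and 10 largest falls among called genes, and for each shRNA and interaction contrast the 10 largest called changes each way. The arrays of the compared groups had to be fully separated, except for the interaction and the average over times. Members of the fixed lists could also be named. On simulated arrays with 200 changed genes among 13916, the fit called 76% of log2 changes of 1 and 98% of log2 changes of 2 for KCl at 6 h with control shRNA. It called 82% and 98% for c-Fos shRNA at 0 h, and 54% and 87% for the interaction at 6 h.

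The replicate numbers come from the array labels. The difference between replicate 1 and replicate 2 was correlated across genes between groups, and all 28 pairs of groups gave a correlation over 0.1, from 0.36 to 0.60 with a median of 0.48. The numbers were therefore taken to pair the arrays. The main analysis has no block, and values with the replicate number as a block are given beside a result where they change its call or move a count by more than 1.5 times. Alternatives covered the normalization, the pseudocount, the filter, the choice of probe sets, the variance model, array weights, the block, a 2-fold threshold, fits on the compared arrays alone and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.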

Results

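The 16 arrays compared mouse cortical neurons carrying an shRNA against c-Fos with neurons carrying a control shRNA, before and during depolarisation with KCl. KCl opens voltage-gated calcium channels and is a standard way to mimic neuronal activity in culture. c-Fos, the product of Fos, is a subunit of the AP-1 transcription factor. The design asks which genes respond to KCl, which genes differ with less Fos mRNA, and whether the KCl response itself differs. Each of the 8 groups had 2 arrays, and the 2 arrays of a group correlated at 0.9906 to 0.9939 across the tested genes.

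Fos was lower with c-Fos shRNA at every time, and rose with KCl in both arms. With control shRNA its deposited intensity went from 246 ± 20.5 (SD, n = 2) at 0 h to 14676 ± 60.5 at 1 h, 13473 ± 233 at 3 h and 11929 ± 44.5 at 6 h. With c-Fos shRNA it went from 135 ± 23.6 to 8675 ± 1340, 4030 ± 377 and 3241 ± 140. The reduction was 45.2% at 0 h, 40.9% at 1 h, 70.1% at 3 h and 72.8% at 6 h. On the log2 scale this was -0.77 at 0 h (limma adjusted p = 0.000172), -0.75 at 1 h (adjusted p = 0.000242), -1.74 at 3 h (adjusted p = 5.66e-07) and -1.85 at 6 h (adjusted p = 5.22e-07), each with a standard error of 0.10. At 1 h the control arrays placed Fos at the 99.4th percentile of the genes, where a probe set can be compressed, and at 0 h all arrays placed it between the 20.8th and the 33.7th, where changes are understated, so whether the reduction deepened with time was not settled.

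**Figure D1:**
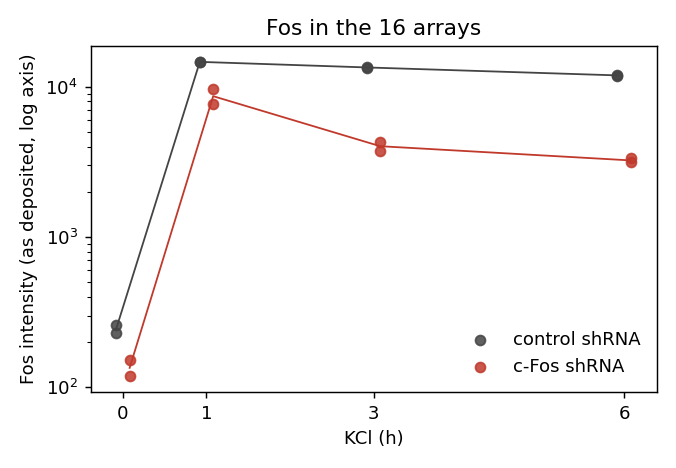
Deposited Fos intensity (log axis) in each of the 16 arrays against hours of KCl, with control shRNA in grey and c-Fos shRNA in red; lines join the means of the 2 arrays. The c-Fos shRNA arrays lie below the control arrays at each time, by 40.9% at 1 h and 72.8% at 6 h.

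KCl for 1 h raised the immediate early genes of control shRNA neurons. The transcription factor genes Fosb (log2 change 6.98 ± 0.22, standard error) and Npas4 (6.35 ± 0.09) rose most, followed by Fos (5.83), Junb (5.17), Egr4 (4.78), Maff (4.71), Nr4a1 (4.56), Egr1 (4.46), Ier2 (3.97), Klf4 (3.95) and Egr2 (3.79). Arc, which encodes a postsynaptic protein, rose by 4.37, the stress-response gene Gadd45b by 3.84, the secreted neuropeptide precursor gene Vgf by 3.87 and Btg2 by 3.66. All 18 early-response transcription factors and 12 of 14 early-response signalling and effector genes rose, also adjusted over the list alone (camera adjusted p = 3.84e-96 and 1.02e-43, and with an estimated correlation adjusted p = 5.36e-05 and 8.59e-06). Of 15 late effectors, 7 rose, and 8 adjusted over the list alone. Txnip, an inhibitor of thioredoxin and glucose uptake, fell most (-2.02 ± 0.25), and Zfp87 (-1.34), Zfp712 (-1.16) and Zfp708 (-1.09), which encode zinc-finger proteins, also fell. Of 13916 genes 319 were higher and 115 lower, 108 and 13 of them by at least 2-fold. With the replicate number as a block 1134 genes were called, 628 higher and 506 lower, leaving out 1 of the 4 arrays gave 227 (without control 1 h replicate 1) to 306, and without further normalization the split was 357 higher and 59 lower.

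After 3 and 6 h of KCl more genes of control shRNA neurons were called than at 1 h, among them most late effectors. Bdnf, a neurotrophin gene, rose by 2.18 at 1 h, 5.01 at 3 h and 5.71 ± 0.23 at 6 h, and Pcsk1, a prohormone convertase gene, by 1.19, 3.99 and 5.00. At 6 h Vgf (4.93), Crem (4.10), the small heat shock protein gene Hspb3 (4.09), Sertad1 (3.95), the neuropeptide gene Cartpt (3.68), Grasp (3.61) and Mlf1 (3.61) were among the largest rises, beside Npas4 (5.40), Fosb (4.65), Atf3 (4.36), Maff (4.35) and Junb (3.93). Late effectors called higher numbered 14 of 15 at 3 h and 13 at 6 h, including Nptx2 (3.39 at 6 h), which encodes a synaptic pentraxin, Crh (3.43), Acan (3.29) and Serpinb2 (3.09). Adjusted over the list alone the count at 6 h was 14. The early-response transcription factors stayed higher, 18 of 18 at 3 h and 17 at 6 h, with smaller changes for Egr1 (4.46 at 1 h and 1.85 at 6 h), while Arc went from 4.37 to 1.27. Large falls included Zkscan4 (-3.0), Zc3h6 (-2.69), Zfp82 (-2.59), Txnip (-2.57), Zfp759 (-2.47) and Zfp60 (-2.45) at 3 h, and Zfp759 (-2.62), Zmat1 (-2.60), Zc3h8 (-2.56), Borcs5 (-2.46) and Rps6ka5 (-2.32) at 6 h. At 3 h 1529 genes were higher and 2685 lower, and at 6 h 2328 higher and 3805 lower, of which 619 and 780 changed by at least 2-fold.

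In several smaller lists single genes changed with KCl in control neurons, and none of the list calls below was kept with an estimated correlation. Neuropeptide genes called higher numbered 6 of 13 at 3 h and 7 at 6 h, among them Adcyap1 (2.74 at 6 h), Tac1 (2.49), Penk (1.43) and Cort (1.16). Their camera adjusted p at 6 h was 0.00028, and 0.208 with an estimated correlation. Of 12 cholesterol synthesis genes 6 rose at 3 h, including Sc5d (1.41), Cyp51 (0.83) and Idi1 (0.73), and Dhcr7 fell (-0.70). Their camera adjusted p was 0.00012, and 0.403 with an estimated correlation. In the unfolded protein response list 7 of 14 genes rose and 2 fell at 3 h, led by the stress genes Chac1 (2.30), Herpud1 (1.81) and Trib3 (1.61) (camera adjusted p = 0.0148, and 0.0746 with an estimated correlation). At 6 h 7 of 11 ionotropic receptor genes fell, with Gria3 at -1.02, Gria4 at -0.84 and Gria1 at -0.53 (camera adjusted p = 0.0407, with an estimated correlation adjusted p = 0.311, and with the replicate block adjusted p = 0.0795). Potassium channel genes split at 6 h, 5 of 11 higher and 2 lower, with Kcna1 at 2.89, Kcnf1 at 2.44 and Kcna4 at 1.96 (camera adjusted p = 0.0208, and 0.384 with an estimated correlation). In glycolysis 4 of 11 genes rose and 1 fell at 6 h, with the glucose transporter genes Slc2a1 at 2.84 and Slc2a3 at 1.02 and hexokinase gene Hk2 at 1.33 (camera adjusted p = 0.0158, and 0.357 with an estimated correlation).

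KCl raised many of these genes in c-Fos shRNA neurons too. At 1 h Fosb (6.48), Npas4 (6.09), Egr4 (5.14), Junb (5.13), Maff (4.44), Egr2 (4.42), Gadd45b (4.36) and Nr4a1 (4.29) were among the largest rises. At 6 h Pcsk1 (5.40), Npas4 (5.22), Fosb (5.12), Bdnf (4.84), Maff (4.44), Crem (4.06), Junb (4.0), Cartpt (3.81), Nppc (3.50) and Crh (3.27) were among them. Early-response transcription factors other than Fos were called higher in 17 of 17 cases at 1 h and 16 at 3 and 6 h, and late effectors in 6, 14 and 13 of 15. Txnip (-2.54 at 1 h), Zkscan4 (-2.79 at 3 h), Zfp759 (-2.69 at 3 h) and Borcs5 (-2.39 at 6 h) fell here too. Higher genes numbered 273 at 1 h, 1380 at 3 h and 2236 at 6 h, and lower genes 195, 2542 and 3467. Of these, 217, 1084 and 1695 higher genes were also called higher with control shRNA, where independent lists would share 6, 152 and 374. The arms share no arrays, but they share the normalization and each gene's estimate of spread, so the lists are not fully independent. Across all genes the changes of the arms correlated at 0.736, 0.877 and 0.871, genes not being independent replicates. With the replicate block 1159 genes were called at 1 h, 569 higher and 590 lower so that the majority turned, and 5972 at 3 h, and leaving out 1 array gave 238 (without c-Fos 0 h replicate 1) to 354 at 1 h. Inhibitory neuron markers, 5 of 9 called higher at 6 h including Gad1 (0.75) and Gad2 (0.58), had a camera adjusted p of 0.0257, of 0.111 with an estimated correlation, and of 0.098 with the replicate block.

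**Figure D2:**
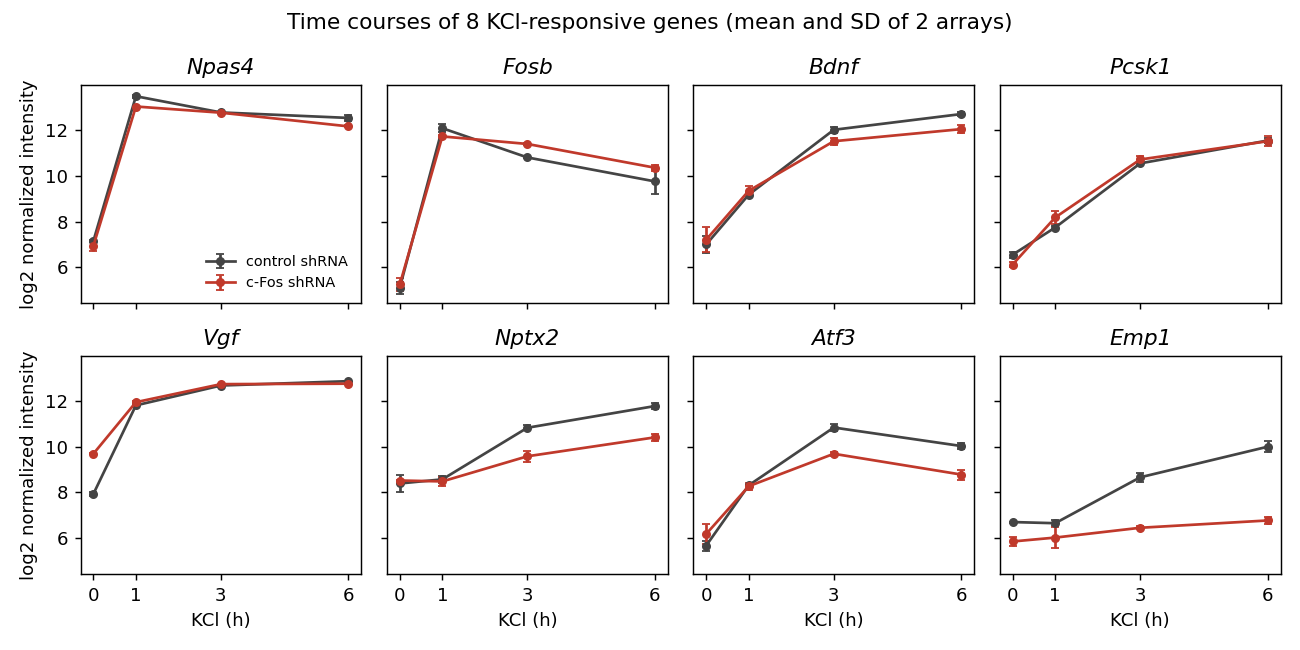
Normalized log2 intensity of 8 genes against hours of KCl, mean and SD of 2 arrays, with control shRNA in grey and c-Fos shRNA in red. Npas4, Fosb and Pcsk1 rose in both arms, with 6 h differences of -0.38, 0.61 and -0.03 of which that of Npas4 was called, Vgf was 1.76 higher at 0 h with c-Fos shRNA and differed by -0.10 at 6 h, and the 6 h differences of Nptx2, Atf3 and Emp1 were -1.37, -1.24 and -3.23.

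The c-Fos and control arms already differed before KCl, in 1675 genes higher and 1428 lower at 0 h. Higher with c-Fos shRNA were Gpd1l (2.47 ± 0.19), Txndc5 (2.39), the prion protein gene Prnp (2.35 ± 0.30), Fstl1 (2.31), Ust (2.14), B3glct (2.14), Smim13 (2.04) and Pik3r3 (1.86). Lower were Akr1c18, a steroid-converting aldo-keto reductase gene (-2.95 ± 0.48), Calb1, which encodes the calcium-binding protein calbindin (-2.69 ± 0.11), the estrogen receptor gene Esr1 (-2.10), the neuropeptide gene Grp (-2.05), Fam149b (-2.04), Dtd1 (-1.99), Lpgat1 (-1.91) and Rgs17 (-1.83). Vgf was higher by 1.76 ± 0.06 at 0 h and the AMPA receptor subunit gene Gria3 by 1.46. Differences of at least 2-fold were seen in 221 higher and 129 lower genes. The other counts were 1498 higher and 1391 lower at 1 h, 1729 and 1512 at 3 h, and 1860 and 1452 at 6 h. Without further normalization the split at 1 h turned to 1243 higher and 1344 lower, and with each array shifted to one median that at 0 h was 1898 and 1112.

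Part of these differences was called at every time. Of 5158 genes called at 1 or more times, 902 were higher and 692 lower at all 4, and 43 were called in opposite directions at different times. Of the genes called at 0 h, 1097 higher and 818 lower were called the same way at 6 h, on other arrays, where independent lists would share 224 and 149. Here too the normalization and each gene's estimate of spread are shared. On the average over the 4 times 3513 genes were higher and 3154 lower, including Prnp (2.74 ± 0.15), Gpd1l (2.57), Smc2os (2.2), B3glct (2.19), Pigq (2.11) and Npnt (2.01), and Akr1c18 (-2.75 ± 0.24), Grp (-2.39), Dtd1 (-2.15), Fam149b (-2.13), Lpgat1 (-1.99) and Calb1 (-1.97). For 307 genes called at 1 h with at least 2-fold differences, the median difference in the same direction was 1.22 at 0 h, 1.27 at 3 h and 1.09 at 6 h. At 6 h the epithelial membrane protein gene Emp1 (-3.23 ± 0.21), the transporter gene Slc16a6 (-2.43), Nceh1 (-2.40) and the GTPase gene Rrad (-2.03) were among the lowest. The 18S rRNA 3′ control probe set also parted the arms, with an intensity of 4241 ± 241 (SD, n = 8) with c-Fos shRNA and 5126 ± 279 with control shRNA (exact two-sided permutation p = 0.000155, the smallest 8 against 8 arrays can give, adjusted p = 0.00108 over 7 array measures). The 18S 5′ and mid signals were lower with c-Fos shRNA too, at 6249 ± 962 against 7782 ± 1420 and 3146 ± 594 against 4042 ± 923. Their exact permutation p was 0.0263 and 0.039, with an adjusted p of 0.091 for both, and these tests did not pair arrays by replicate number. The 3′ to 5′ ratio of Actb was 1.193 ± 0.0108 against 1.209 ± 0.0189 (exact permutation p = 0.0606). With the replicate block 5396, 5265, 5628 and 5779 genes were called at 0, 1, 3 and 6 h, and the lowest counts with 1 array left out were 1868, 1590, 1907 and 2101, each without replicate 1 of the control arrays of that time.

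**Figure D3:**
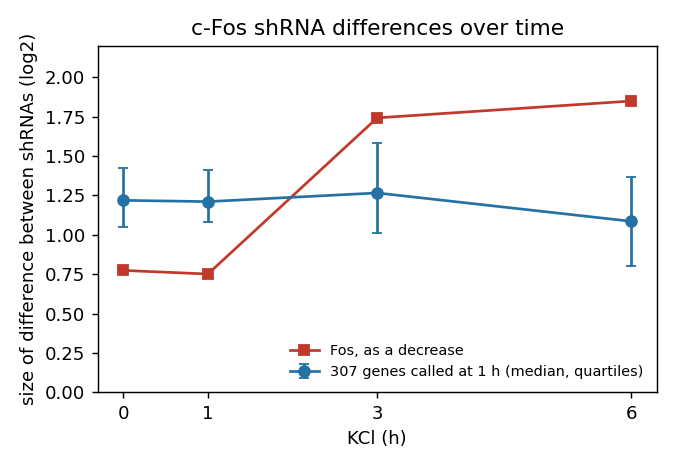
Size of the difference between c-Fos and control shRNA (log2) against hours of KCl, for 307 genes called at 1 h with at least a 2-fold difference (blue, median and quartiles, in the direction at 1 h) and for Fos (red, as a decrease). The median of the genes was 1.22 at 0 h and 1.09 at 6 h; the genes were picked at 1 h, and the Fos values at 0 and 1 h can be understated.

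Of the fixed lists, 4 tests called a list between the arms at single times, none of them with an estimated correlation. In the unfolded protein response list 9 of 14 genes were higher and 2 lower at 0 h with c-Fos shRNA, including Chac1 (1.34), Trib3 (1.10) and Manf (1.06), with Hspa5 lower (-0.75). Its camera adjusted p was 0.0482, 0.255 with an estimated correlation, and 0.143 with the replicate block. At 6 h 4 of 14 early-response signalling genes and 4 of 15 late effectors were lower, among them Ptgs2, which encodes cyclooxygenase 2 (-1.46), Nptx2 (-1.37), Gpr3 (-1.10) and Arc (-0.68), both lists with a camera adjusted p of 0.0103 and of 0.15 with an estimated correlation. Adjusted over the list alone the counts were 6 and 7. At 1 h 3 of 17 early-response transcription factors were lower and 1 higher, 8 and 1 adjusted over the list alone (camera adjusted p = 0.0462, and 0.963 with an estimated correlation).

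The KCl response itself differed between the arms for 6 genes at 1 h, 56 at 3 h, 172 at 6 h and 121 by the F test over the 3 times. At 6 h 109 genes responded lower with c-Fos shRNA and 63 higher. The lower responses were led by Emp1 (-2.39 ± 0.30), Cav1, which encodes caveolin (-1.88 ± 0.22), the stress-induced pseudokinase gene Trib3 (-1.87), Vgf (-1.86 ± 0.09), Egr3 (-1.83 ± 0.25), C2cd4b (-1.77), Atf3 (-1.75 ± 0.27), Htra4 (-1.72), Ang (-1.67) and Blnk (-1.67). A dimmer second probe set of Emp1 and of Egr3 went the other way at 6 h and was not called, as given below. Nptx2 (-1.51 ± 0.25), Slc2a1 (-1.12), the cell cycle inhibitor gene Cdkn1a (-0.98), the phosphatase gene Dusp6 (-0.83) and the potassium channel gene Kcnf1 (-0.71) were also lower. Higher were Smc2os (1.65 ± 0.34), the thyrotropin receptor gene Tshr (1.5 ± 0.23), Ddias (1.07), Calb1 (1.04 ± 0.16), Epb41l4b (1.03), the synaptic adhesion gene Lrrtm3 (0.98), Cdk12 (0.98) and the neuronal tubulin gene Tubb3 (0.48). Smc2os is dim, with control log2 means of 6.57 at 0 h and 4.75 at 6 h, the latter below the filter threshold of 5.786. Htra4 is dim too (6.0 and 6.98). Fos changed by -0.97 at 3 h and -1.08 at 6 h, and by 0.02 at 1 h.

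Several of these genes were already called at 1 or 3 h. The interactions at all times subtract the same 0 h arrays, so a difference at 0 h enters each of them and the calls are not independent. At 1 h Vgf (-1.61 ± 0.09), Grasp (-1.01), Dusp6 (-0.96), Kcnf1 (-0.73) and Emd (-0.73) responded lower and Tgoln1 (0.79) higher. At 3 h the lower responses were led by C2cd4b (-1.96), Trib3 (-1.92), Vgf (-1.70), Atf3 (-1.66), Nptx2 (-1.39), Cav1 (-1.37), Pdgfc (-1.37), Egr3 (-1.36), Dusp14 (-1.31) and Pik3r3 (-1.28), and the higher ones by Calb1 (1.14), Fbxo28 (1.01) and Cdk12 (0.94). The arms reached these interactions differently. Vgf and Cav1 were higher at 0 h with c-Fos shRNA, by 1.76 and 1.63, and at 6 h differed by -0.10 and -0.24, which was not called. Nptx2 and Atf3 differed by 0.14 and 0.51 at 0 h, not called (for Atf3 the adjusted p was 0.0786, and 0.0276 with the replicate block), and by -1.37 and -1.24 at 6 h, both called. Emp1 was lower at both times, and Egr3 and Trib3 were higher at 0 h and lower at 6 h. Of the 109 genes, 92 rose with KCl in control neurons, 64 were higher with c-Fos shRNA at 0 h and 66 lower at 6 h. Of the 63 genes with a higher response at 6 h, 41 fell with KCl in control neurons and 10 rose. With c-Fos shRNA 43 of the 63 were lower at 0 h and 25 higher at 6 h. A lower start therefore enters many of the higher responses. With the replicate block 28, 560 and 1582 genes were called at 1, 3 and 6 h and 1401 by the F test. Leaving out 1 array gave 1 to 4, 14 to 50, 40 to 95 and 39 to 123 genes, lowest at 6 h without control 0 h replicate 1, and with each array shifted to one median the split at 6 h was 33 higher and 104 lower. With the block the calls were 3 higher and 25 lower at 1 h but near evenly split later, 276 and 284 at 3 h and 798 and 784 at 6 h, so over all genes the excess of lower responses at 3 and 6 h was not kept.

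**Figure D4:**
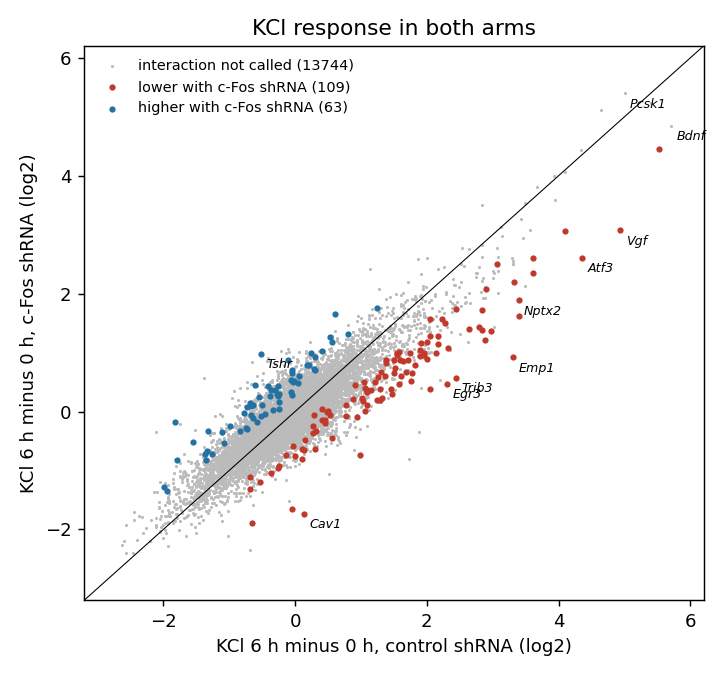
Log2 change from 0 to 6 h of KCl with c-Fos shRNA against that with control shRNA, 1 point per gene, with the line of equal change. The 109 genes with a lower response under c-Fos shRNA (red) and the 63 with a higher one (blue) lie to either side of the line.

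The early-response transcription factors were called one by one in few cases. At 6 h 3 of the 17 other than Fos did, namely Egr3, Atf3 and the orphan receptor gene Nr4a3 (-0.57), and 6 did adjusted over the list alone, while Fosb (0.47), Junb (0.07), Npas4 (-0.17) and Maff (0.10) were not called. Their camera adjusted p was 0.000316, and 0.278 with an estimated correlation. AP-1 subunits other than Fos had a median of -0.52 at 6 h, where Atf3 was called and 6 of 10 were adjusted over the list alone. Higher starting levels enter these values, since only Junb had a lower log2 mean at 0 h with c-Fos shRNA (7.56 against 7.76). Fosl2 stood at 10.61 against 9.68 at 0 h and at 12.45 against 12.33 at 6 h. Nr4a3 was likewise above control at both times, at 11.08 against 10.06 and 13.58 against 13.13. These levels come from 1 probe set per gene. With the mean of a gene's probe sets the difference between the arms was -0.18 for Fosl2 on average over the 4 times. For Nr4a3 it was -0.031 at 1 h and -0.073 at 3 h. Fosl2 (-0.82) and Jun (-0.64) were not called, with adjusted p = 0.108 and 0.224, and 0.0167 and 0.000712 with the replicate block. AP-1 subunits, late effectors (median -0.49), early-response signalling genes (median -0.27) and the unfolded protein response (median -0.33, after a median of 0.46 between the arms at 0 h) each had a camera adjusted p at 6 h of 0.0412 with an estimated correlation. Bdnf changed by -0.87 at 6 h, which was not called (adjusted p = 0.237, and 0.00567 with the replicate block), and Pcsk1 by 0.40.

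KCl-induced genes as a set had a lower KCl response with c-Fos shRNA. The median interaction was -0.25 for 97 genes at 1 h, -0.16 for 328 genes at 3 h and -0.23 for 530 genes at 6 h, and 72, 205 and 372 of them lay below 0. The camera p was 7.13e-14, 1.05e-10 and 3.44e-14, and with an estimated correlation p = 0.00132, 0.00239 and 0.00228. These tests share the 0 h arrays and are not independent of one another. At 6 h the induced genes rose by a median of 1.53 with control shRNA and 1.29 with c-Fos shRNA, and 54 of them responded lower and 3 higher when called singly, 156 and 27 with the replicate block (camera p = 1.25e-13 with the block, and 0.00708 with the block and an estimated correlation). Genes picked by their rise with c-Fos shRNA alone gave a limma interaction median of -0.13 at 1 h (camera in limma, p = 3.94e-06, and 0.0304 with an estimated correlation). The median was 0.01 at 3 h (camera p = 0.137) and -0.05 at 6 h (camera p = 0.00625, and 0.124 with an estimated correlation). Genes picked by their rise with control shRNA alone gave medians of -0.29, -0.28 and -0.35 at 1, 3 and 6 h. Their p from camera with an estimated correlation was 0.000446, 0.000358 and 0.000221. Picking on 1 arm reuses its arrays in the interaction. That tilts the median upward for c-Fos shRNA and downward for control shRNA.

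Markers of other cell types and of virus response were measured in the same way. Medians between the arms at 0 h were -0.07 for 10 astrocyte genes, 0.05 for 7 oligodendrocyte lineage genes, 0.04 for 8 vascular and fibroblast genes, 0.05 for 9 progenitor genes, -0.08 for 8 excitatory, -0.09 for 9 inhibitory and -0.05 for 11 pan-neuronal genes. Members differed within the lists, with interquartile ranges from 0.141 to 0.591 (excitatory), and 3 excitatory, 3 pan-neuronal and 1 astrocyte gene were called lower and none higher. None of these lists, the interferon response list or the postsynaptic scaffold list was called between the arms at any of the 4 times by camera. Only 8 of 18 interferon response genes were tested. The p53 and apoptosis list and the genes described as AP-1 targets were called in none of the contrasts, although single members moved, with Cdkn1a (1.95) and Pmaip1 (2.03) rising after 6 h of KCl in control neurons. Only 10 of 16 AP-1 target genes were tested. Mmp9 (5.73), Plaur (6.02), Pdyn (5.79) and Gal (5.93) had log2 means near the filter threshold of 5.786 in control neurons at 0 h. The missing call therefore says little about AP-1 targets. Of the brighter members, Ccnd1 stood at 10.62 with c-Fos shRNA against 11.73 with control shRNA at 0 h, and Dnmt1 at 11.33 against 11.41. After 6 h of KCl Ccnd1 stood at 11.59 against 12.05, Ezr at 11.06 against 11.60 and Penk at 9.64 against 10.20. Cd44 stood at 9.55 against 9.86 and Dnmt1 at 10.83 against 10.84, while the dimmer Timp1 was higher, at 6.37 against 6.17. Microglia markers were too few to weigh, with 3 measured genes. Oligodendrocyte lineage markers after 1 h of KCl, with a median of -0.19 in control and -0.24 in c-Fos shRNA neurons, had camera adjusted p-values of 0.374 and 0.237, and of 0.0395 and 0.00975 with the replicate block.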

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

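The tests of the Fos level at harvest, of cell type markers, of array controls and of the starting level were chosen after the results they measure were seen, while the test of a general weakening was set beforehand.

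The KCl response differed between the arms by a test of the difference itself for 6 genes at 1 h, 56 at 3 h, 172 at 6 h and 121 by the F test. Named genes with such a difference at 1 h were Vgf (-1.61), Grasp (-1.01), Dusp6 (-0.96), Emd (-0.73) and Kcnf1 (-0.73), lower with c-Fos shRNA, and Tgoln1 (0.79), higher. At 3 h they were C2cd4b (-1.96), Trib3 (-1.92), Vgf (-1.70), Atf3 (-1.66), Nptx2 (-1.39), Cav1 (-1.37), Pdgfc (-1.37), Egr3 (-1.36), Dusp14 (-1.31), Pik3r3 (-1.28), Hspb3 (-1.27), Grasp (-1.19), Ang (-1.08), Fos (-0.97), Slc16a6 (-0.96), Cdkn1a (-0.87), Kcnf1 (-0.85), Mlf1 (-0.72) and Emd (-0.68), lower, and Calb1 (1.14), Fbxo28 (1.01), Cdk12 (0.94) and Tgoln1 (0.93), higher. At 6 h they were Emp1 (-2.39), Cav1 (-1.88), Trib3 (-1.87), Vgf (-1.86), Egr3 (-1.83), C2cd4b (-1.77), Atf3 (-1.75), Htra4 (-1.72), Ang (-1.67), Blnk (-1.67), Slc16a6 (-1.60), Nptx2 (-1.51), Grasp (-1.26), Pik3r3 (-1.13), Slc2a1 (-1.12), Ust (-1.09), Fos (-1.08), Pdgfc (-1.07), Hspb3 (-1.03), Txndc5 (-1.01), Mlf1 (-1.0), Cdkn1a (-0.98), Dusp6 (-0.83), Emd (-0.76), Kcnf1 (-0.71) and Nr4a3 (-0.57), lower, and Smc2os (1.65), Tshr (1.5), Ddias (1.07), Calb1 (1.04), Epb41l4b (1.03), Cdk12 (0.98), Lrrtm3 (0.98), Tgoln1 (0.76) and Tubb3 (0.48), higher. A dimmer second probe set of Egr3 and of Emp1 went the other way at 6 h, by 0.76 and 0.57, neither called. With the replicate block 798 genes responded higher and 784 lower at 6 h, against 63 and 109 without it, and of the 530 KCl-induced genes 27 higher and 156 lower.

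Outside the named genes, 4795 probe sets without a gene name passed the same filter, and 372 of them were higher and 356 lower after 6 h of KCl in control neurons.

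The arms differed in 3103 genes before KCl was given. If the Fos mRNA level at harvest set these differences, the 350 genes that differed at least 2-fold at 0 h would move the other way as KCl raised Fos, by about their median difference of 1.223, yet at 6 h the mean response of the arms in that direction had a median of 0.071 (quartiles -0.347 and 0.414), although KCl changes more than Fos. A change in the mix of the listed cell types large enough for these 350 genes would move a marker list by about the same 1.223. The largest absolute median of 7 lists was 0.088, with interquartile ranges up to 0.591. That bar comes from genes picked for at least 2-fold differences, so a smaller change of mix behind smaller differences is not excluded. Microglia and finer neuron subtypes had no list in this comparison, and some excitatory and pan-neuronal markers were called lower. A technical difference between the arms cannot be told apart from the shRNA, since each arm is one shRNA. The 18S rRNA 3′ signal parted the arms (exact permutation p = 0.000155, the smallest 8 against 8 arrays can give). The 18S 5′ signal (exact permutation adjusted p = 0.091 without pairing) also parted them within each replicate number. It was at most 8010 with c-Fos and at least 8933 with control shRNA in replicate 1, and 5789 and 6092 in replicate 2. The mid signal parted them likewise. Between replicate numbers 19 genes differed at least 2-fold, against 327 between the arms. Replicates 1 and 2 differed in the 5′ signal (means 8061 and 5969, exact permutation adjusted p = 0.00254). They were not called in the 3′ one (exact permutation adjusted p = 0.713). The gene counts therefore bear at most on a difference like the 5′ one. They decide nothing about one that goes with the 3′ signal. A lasting effect of less c-Fos before harvest, effects of the shRNA on other transcripts and a difference between virus preparations may also contribute and were not tested.

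Of 108 genes other than Fos with a lower KCl response at 6 h, 43 were not below control at 6 h, and a higher starting level could account for them, all above control at 0 h (median 0.903, and 0.064 at 6 h), although the arithmetic of an interaction nearly fixes that outcome. A higher start alone would leave genes level with control or above. The 65 below control at 6 h were picked against that, so their 6 h level decides nothing. That 44 of them were not called above control at 0 h decides little for the same reason. At 3 h, on arrays whose differences took no part in picking them, the median of the 65 was -0.476 (quartiles -0.85 and -0.165). That argues against a higher start as their whole cause. All arrays did share the normalization and the estimate of spread. A generally weaker response of the c-Fos shRNA cultures would also weaken the falls, and the 647 KCl-lowered genes had a median interaction of 0.104 where 0.204 was predicted. That is 50.8% of the prediction, with 4.23% to 97.1% when 1 array was left out, so a general weakening and a loss at particular genes cannot be told apart here. Less c-Fos at AP-1 sites of particular genes stays open as a biological explanation, untested by these arrays.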

How the results depend on the processing

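Leaving arrays without further normalization was chosen after seeing the data, and all other alternatives were set earlier. Quantile normalization, listed as an alternative, coincided with the main setting. Fits on the compared arrays alone are the same fit for the F test and the 4-time average, and give no other value. Signal over background limits dim probe sets, and a fit without 1 array assumes that the array left alone in its group varies like the other groups. No cause was tested for the changes below, except that a threshold on size can only lower a count.

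With the replicate block 5396, 5265, 5628 and 5779 genes differed between the arms at 0, 1, 3 and 6 h. KCl called 1134 genes at 1 h with control shRNA, and 1159 at 1 h and 5972 at 3 h with c-Fos shRNA, and the interaction 28, 560 and 1582, with 1401 by the F test. In simulated data the block called 7 unchanged genes for the interaction at 6 h and 21 for KCl at 6 h with control shRNA, against 1 without it. Of simulated log2 changes of 1 the block called 78% and 97% in these contrasts, against 54% and 76% without the block. Besides list calls given elsewhere, the block ended those of cholesterol synthesis at 6 h with control shRNA (camera adjusted p = 0.0566), inhibitory neuron markers at 3 h with c-Fos shRNA (0.0613) and in the interaction at 3 h (0.0935), and the unfolded protein response in the interaction at 3 h (0.061). It added glycolysis with c-Fos shRNA at 3 h (0.0123) and 6 h (0.0158) and excitatory neuron markers at 6 h (0.0285). It ended no call of a named gene and changed no other call printed here.

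With a 2-fold threshold the arms differed in 350, 307, 432 and 363 genes, and in 327 on average. KCl called 121, 845 and 1399 genes with control shRNA and 119, 733 and 1068 with c-Fos shRNA, and the interaction 2, 21 and 44. With every probe set tested the arms differed in 5067 at 3 h, 5080 at 6 h and 11232 on average. KCl called 783, 6808 and 10216 with control shRNA and 751, 6119 and 9432 with c-Fos shRNA, while the interaction called 2, 49 and 146 and the F test 105. With only the compared arrays the arms differed in 1704 genes at 1 h and 2130 at 6 h, KCl at 1 h called 184 with control and 170 with c-Fos shRNA, and the interaction 1, 7 and 13. With the mean of a gene's probe sets the interaction called 3, 31 and 82 genes and the F test 60. With no variance trend it called 1 at 1 h. Genes picked as induced on the c-Fos shRNA arrays gave a median interaction of 0.012 at 3 h, the reverse sign, under a choice that tilts the median upward.

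Leaving out 1 array gave 1868 to 2493 genes between the arms at 0 h, 1590 to 2177 at 1 h, 1907 to 2687 at 3 h, 2101 to 2634 at 6 h and 6077 to 6534 on average. Besides replicate 1 of the control arrays of each time, c-Fos 0 h replicate 1 (2004), c-Fos 3 h replicate 1 (2149) and c-Fos 6 h replicate 2 (2199) moved these counts by over 1.5 times. KCl with control shRNA gave 227 to 306, 3046 to 3492 and 4997 to 5398, with 247 without control 0 h replicate 1 and 276 without control 1 h replicate 2. KCl with c-Fos shRNA gave 238 to 354, 2680 to 3170 and 4386 to 4870, with 307 without c-Fos 0 h replicate 2 and 273 without c-Fos 1 h replicate 1. The interaction gave 1 to 4, 14 to 50, 40 to 95 and, by the F test, 39 to 123. At 6 h it gave 40 and 95 without control 0 h replicates 1 and 2, 54 and 84 without control 6 h replicates 1 and 2, 65 and 73 without c-Fos 0 h replicates 1 and 2, and 77 and 59 without c-Fos 6 h replicates 1 and 2. At 3 h it gave 14 without control 3 h replicate 1, and at 1 h 1 without c-Fos 0 h replicate 1. The medians of the KCl-induced genes ran from -0.291 to -0.15, -0.256 to -0.126 and -0.336 to -0.179, and the number of list tests called from 61 to 72, against 66.

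Among lists, the median reversed for cholesterol synthesis in the interaction at 6 h (-0.002 without c-Fos 6 h replicate 2 and 0.192 without replicate 1), glycolysis at 3 h with control shRNA (-0.003 without control 3 h replicate 2 and 0.213 without replicate 1) and in the interaction at 6 h (0.007 without control 6 h replicate 2 and -0.366 without replicate 1), and inhibitory neuron markers in the interaction at 3 h (-0.009 with a median shift). The unfolded protein response at 1 h with control shRNA, with a median of -0.029 and a mean of 0.156, gave 0.045 with a median shift, 0.033 with no further normalization, 0.115 with the mean of probe sets, and -0.03, 0.08, 0.155 and 0.026 without control 0 h replicates 1 and 2 and control 1 h replicates 1 and 2. In the interaction at 3 h it gave 0.018 without c-Fos 0 h replicate 1 and -0.201 without replicate 2. With the mean of a gene's probe sets Fbxo28 reversed at 3 and 6 h of KCl with control shRNA (0.064 and 0.34), Lpgat1 at 3 and 6 h with c-Fos shRNA (0.043 and 0.42) and with control shRNA (0.15 and 0.058), and between the arms Lrrtm3 at 3 h, 6 h and on average (-0.18, -0.011 and -0.23), Nr4a3 at 1 and 3 h (-0.031 and -0.073), Fosl2 on average (-0.18) and Epb41l4b at 6 h (-0.093). Epb41l4b also reversed with a pseudocount of 64 (-0.21) and without c-Fos 6 h replicates 1 and 2 or control 6 h replicate 1 (-0.022, -0.526 and -0.433). On the probe set of the main fit its 6 h log2 means were 7.92 ± 0.06 (SD) with c-Fos and 7.49 ± 0.12 with control shRNA. Leaving out 1 such array cannot turn that sign, so another probe set must have represented the gene in these fits. Of other settings of list tests 5000 were the same, 65 gained a call and 58 lost one, and of named genes 25681, 326 and 770.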

Other observations

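The zinc-finger tests below were chosen after single zinc-finger genes were seen among the largest falls, with their predictions set before the group was measured.

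Zinc-finger genes with symbols made of Zfp, Zscan, Zkscan, Zik or Znf and a number, 330 in all, fell as a group after 3 h of KCl in both arms. Zinc-finger genes with other names were not in this group, and some of them, such as Egr1 and Klf4, rose. At 3 h with control shRNA 202 were lower and 21 higher, 61.2% lower against 19.3% of all genes, and with c-Fos shRNA 181 and 15. Zkscan4 (-3.0), Zfp82 (-2.59), Zfp759 (-2.47) and Zfp60 (-2.45) were among the lowest. The camera p at 3 h was 9.15e-17 and 1.96e-14, and with an estimated correlation p = 0.00471 and 0.00733. At 1 h 32 and 68 were lower and 8 and 5 higher (with an estimated correlation p = 0.0158 and 0.00339). At 6 h 164 and 131 were lower and 31 and 32 higher, with p = 0.0688 and 0.198 with an estimated correlation.

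Expression level is argued against, as the group's median at 3 h with control shRNA was -0.541 and those of 10000 lists matched on level ran from -0.147 to 0.015. Quantile normalization is argued against too, since relative to all genes the median was -0.488, and -0.521 without further normalization. A hypothesis is that many of these transcripts are short-lived and may fall when transcription turns to activity-induced genes. Transcript stability was not measured here, so that hypothesis stays untested.

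The number of genes that differed between the arms was set against other splits of the arrays within each time. Of 100 splits drawn from 648, the real one included, 1 gave as many genes, the real split with 6661 genes in an additive fit. That is under 5 of 100, the limit set beforehand, but also the smallest share such a draw can give. Most of the drawn splits part the replicate numbers unevenly at 1 or more times, unlike the real one. Among the drawn splits that part the paired arrays as the real one does, 1 of 22 gave as many, the real split. That share of 4.55% is the smallest that 22 splits can give. Chance is therefore not excluded, although no other drawn split called as many genes. The highest other split gave 3704 genes, equalled the real split at 3 of 4 times and had both replicate numbers on each side, as 21 of the drawn others did. The highest of the splits equal to the real one at fewer times gave 1920, and the median of the others was 0.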
